A study of Arabidopsis thaliana with 7 samples.

How the data were processed

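RNA of whole seedlings was compared on 7 Agilent 2-colour oligonucleotide arrays, each of which held 1 biological replicate under estradiol and 1 under DMSO. The arrays fell into a Col-0 line (3 arrays) and a cuc1 line (4 arrays), as the labels gave them, and labels, scanner files and the deposited matrix were matched array by array. The orientation of each array was taken from its labels and tested against the deposited matrix, whose columns correlated with the scanner log ratios, turned to estradiol over DMSO, at 0.974 to 0.9996.

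Scanning and image analysis were done by the authors with Agilent Feature Extraction 9.1.3.1, per the submitters' processing notes. The deposited scanner files gave the spot and local background intensity as median pixel values of Cy3 and Cy5, without subtraction, per the file headers. They also gave a log10 ratio of Cy5 over Cy3 after the software's own background subtraction and dye normalization, per the file headers, and flags for outlying, saturated and dim spots. The deposited series matrix held log2 ratios of estradiol over DMSO, normalized by the authors with a method that the labels did not state, and its columns had medians from -0.109 to 0.0939. The files of the cuc1 arrays held no mean signal, so the median signal was used for all 7 arrays, which was the fallback set in advance.

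The analysis used R 4.3.3 with limma 3.58.1, statmod 1.5.0 and data.table (version 1.17.8), and the figures used Python 3.11.15 with matplotlib 3.10.9. Median signals were corrected for background by the normexp method with an offset of 50, and log2 ratios of Cy5 over Cy3 were normalized by loess within each array, with control spots given no weight. Spots called outliers in either channel, 160 to 557 per array, were set to missing. Of 37685 spots that were not controls, the spots of 1 probe were averaged to 37478 probes, of which 26236 had a locus and 11242 had none. A probe was tested if it was well above background in at least 1 channel on at least 3 of the 7 arrays, which 25051 were. Of several passing probes of a locus, as for 467 loci, the one with the highest average signal stood for the gene. This left 24559 features, 21221 genes with a locus and 3338 probes with none. Names came from the array files and from the RefSeq gene table of the TAIR10.1 assembly, in which 21098 of the tested loci (99.4%) were found. No coordinates were used.

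A single limma fit held 1 coefficient for the effect of estradiol in each line and 1 for the dye of each feature, with moderated tests on 4 residual and 3.62 prior degrees of freedom. The difference between the lines was the Col-0 coefficient minus the cuc1 coefficient. Since the Col-0 arrays shared 1 dye orientation, this difference equalled the mean of the Col-0 arrays minus the mean of the 2 cuc1 arrays of that orientation, within 1e-06 for all 24437 features with a value. Features whose coefficient could not be estimated because of missing spots got no value, which left 24404, 24458 and 24437 for the Col-0 line, the cuc1 line and the difference. The dye coefficient had a median size of 0.0894 on the log2 scale. In limma, 0 of 24458 features had a dye effect at an adjusted p under 0.05, and 4808 at an unadjusted p under 0.05. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each of the 3 comparisons, at 0.05. Errors are standard errors of the fit unless named SD. Line and slide coincided, so signal levels were not tested between the lines.

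Gene lists, 23 in number with 308 distinct loci, were tested by limma's camera with a preset inter-gene correlation of 0.01, on the 23437 features with a value on every array, and by fry. Members called were also counted when adjusted over the list alone. A second camera test used the correlation estimated from the data. The genes named were chosen by a rule. For each comparison it took the 10 largest positive and 10 largest negative log2 changes with an adjusted p under 0.05 and, within a line, the same sign on every array. It added TCP3, CUC1, CUC2, CUC3, MIR164A, AS1, IAA3, SAUR65, LOX2, ARR16, LOB, STM and KNAT1, and up to 4 members of each list with the smallest p. The lists, this rule, the model, the filter and all alternatives but 1 were chosen before the data were examined. Gene families named by their annotation, 25 in number, and the copper genes were chosen after it.

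Alternatives took the scanner software's own log ratios or the deposited matrix values, left out background subtraction, or put median centring in place of loess. Others used no filter on dim probes or required signal in both channels on all 7 arrays, which gave 36907 and 20578 features. Others left out the dye term, fitted each line alone, averaged the probes of a locus, kept outlying spots, left out each array in turn, or used the replicate number as a block, fixed in place of the dye term or random beside it. A minimum of a 2-fold change and the estimated correlation completed the planned ones. A slide block was not run, because each slide held 1 line only. Scaling each array to a common spread was added after the data were seen. Gene set collections, sequence motifs and promoter sequences were not analysed here.

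The orientation of ratios, the fit and camera were tested on simulated log ratios, with 50 changed features at each of 4 sizes among 24559 in each comparison. Background correction, loess, the handling of outlying spots and the filter were not simulated. Far fewer features changed in the simulation than were called in the data (56.1% in the Col-0 line, 58.7% in the cuc1 line and 14.2% in the difference). The adjustment of p was therefore stricter, and the recovered shares do not carry over to the data. At log2 changes of 0.5, 1, 2 and 3 the fit recovered 32%, 78%, 96% and 98% in the Col-0 line, with 9 false among 161 calls. It recovered 66%, 94%, 98% and 100% in the cuc1 line, with 9 false among 188 calls, and 10%, 72%, 92% and 96% of the differences, with 5 false among 140. A list of 8 genes shifted by 1 was called in each comparison by camera (adjusted p = 3.7e-23, 3.9e-36 and 6.9e-23), and 0 of the other lists were. Noise was simulated independently for each gene, and list members were drawn at random. The simulation therefore cannot show how the preset correlation performs where members vary together. In the data the estimated correlation was 0.69 for photosynthesis and 0.49 for SAUR genes. Repeated spots of 23 probes within an array differed by a median of 0.0328 to 0.0698 on the log2 scale.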

Results

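Transcript levels were compared in whole Arabidopsis thaliana seedlings, 10 days after germination, that carried pXVE:TCP3-SRDX. This transgene places TCP3, a leaf growth regulator of the TCP family of transcription factors, under an estradiol-inducible promoter and joins it to the SRDX repression domain, which turns it into a chimeric repressor. The transgene was studied in the Col-0 accession on 3 arrays and in the cuc1 mutant on 4 arrays. Each 2-colour Agilent array carried 1 biological replicate treated for 24 h with 5 µM estradiol and its partner treated with the solvent DMSO. Estradiol samples were labelled with Cy5 on the 3 Col-0 arrays and on cuc1 replicates 1 and 2, and with Cy3 on cuc1 replicates 3 and 4. The description of Col-0 replicate 3 gave a harvest after 36 h, against 24 h in its other labels, and the growth protocol of cuc1 replicates 1 and 2 gave 5 mM estradiol for 1 channel, against 5 µM elsewhere. No estradiol-treated seedlings without the transgene were among the samples, so each comparison gives the joint effect of the chemical and of the induced repressor.

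Median spot signals lay between 100 and 191.5 in Cy3 and between 195.5 and 323 in Cy5, over local backgrounds of 36 to 51 and 39 to 60. Between 59.1% and 66.9% of spots were well above background in a channel, and 0 spots were saturated. Ratios across probes correlated at 0.957 to 0.986 between Col-0 arrays, at 0.869 to 0.948 between cuc1 arrays and at 0.839 to 0.901 between arrays of different lines. The arrays, 3 and 4 per line, limited the precision. In all, 24559 genes or probes were tested, of which 21221 were genes with a locus.

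The first comparison asked which transcripts changed after induction of the repressor in the Col-0 background. Each fitted change is the mean of the Col-0 arrays minus a dye coefficient. That coefficient came from the cuc1 arrays alone, since the Col-0 arrays shared 1 orientation. The TCP3 signal rose 6.08-fold (log2 2.60 ± 0.11 SE, n = 3, adjusted p = 5.4e-06), and whether its probe read the native gene, the transgene or both was not examined. CUC1, which with CUC2 and CUC3 sets the boundaries between organs, rose 5.75-fold (log2 2.52 ± 0.11, adjusted p = 2.6e-06). CUC3 rose by 1.75 ± 0.08 and CUC2 by 0.75 ± 0.15 on the log2 scale, and both were higher on 3 of 3 arrays. IAA3, a repressor of auxin responses, changed by log2 -3.16 ± 0.15, and AS1, which keeps meristem genes silent in leaves, by -1.98 ± 0.13. LOX2 of jasmonate synthesis changed by -2.08 ± 0.38 and ARR16, a response regulator of cytokinin signalling, by -1.33 ± 0.18. The meristem gene KNAT1 rose by 1.22 ± 0.11 and the boundary gene LOB by 1.04 ± 0.14, whereas STM stood at 0.00093 ± 0.11 with an adjusted p of 0.995. Before the dye coefficient was taken off, STM averaged -0.27 (SD 0.17) on the 3 Col-0 arrays. MIR164A, the precursor gene of a microRNA that targets CUC1 and CUC2, had no probe.

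The 10 largest increases in the Col-0 line among genes with the same sign on every array were led by ARD3, an acireductone dioxygenase, at 430-fold (log2 8.75 ± 0.34, adjusted p = 1.6e-06). They also held FMO1 (log2 6.93) and PNP-A (6.57), which act in defence, PAD3 of camalexin synthesis (6.76), TAT3, an aminotransferase (7.17), and TPPD, a trehalose phosphate phosphatase (6.95). The other 4 were AT5G03350 (7.46), AT5G19880 (6.998), AT5G24200 (6.95) and AT3G28510 (6.60). The 10 largest decreases held 3 genes of the Rubisco small subunit, RBCS2B (-4.94), RBCS3B (-4.56) and RBCS1B (-4.55), whose near-identical sequences leave open which of them each probe read. AT2G10940 (-5.44 ± 0.29), the germin-like genes AT1G72610 (-5.18) and GER3 (-5.14), CYP706A6 (-4.52), PnsL3 (-4.39), MSRB6 (-4.36) and AT2G29290 (-4.24) made up the rest.

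Among 23 gene lists, SAUR, Aux/IAA, class I TCP and photosynthesis genes fell and boundary, NAC and stress genes rose in the Col-0 line. Of 18 SAUR genes, which are induced early by auxin, 0 rose, 17 fell and 1 did not pass (median -2.30, camera adjusted p = 6.0e-09, adjusted p = 0.341 with an estimated correlation). Examples were SAUR14 at -4.02 ± 0.16 and SAUR63 at -3.26 ± 0.14. Whether the probes told related SAUR genes apart was not examined, so the members may not be separate readings. SAUR62 was at least 1.66-fold lower, since its signal under estradiol was not above background. Of 25 Aux/IAA genes, 3 rose, 17 fell and 5 did not pass (adjusted p = 0.00773, and 0.501 with an estimated correlation), with IAA19 at -2.02 ± 0.10 and IAA4 at -1.98 ± 0.14. Of 11 class I TCP genes, 0 rose, 9 fell and 2 did not pass (median -0.85, adjusted p = 0.00392, and 0.175 with an estimated correlation), led by TCP21 at -2.82 ± 0.09 and TCP7 at -2.77 ± 0.11. Of 15 photosynthesis genes, markers of green tissue, 0 rose, 12 fell and 3 did not pass (median -2.40, adjusted p = 0.0115 from 7 members, and 0.501 with an estimated correlation). RCA, the activase of Rubisco, stood at -2.82 ± 0.19. The call of the photosynthesis list ended with the log ratios of the scanner software (adjusted p = 0.0560).

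All 6 measured genes of the list of TCP3 targets named by earlier work fell in the Col-0 line (median -2.20, adjusted p = 0.00105, and 0.175 with an estimated correlation). This list holds genes chosen in part from work on the same system, so it is not independent evidence of their direction. Its members included the cell cycle inhibitor KRP1 at -2.32 ± 0.13 and SAUR65 at -2.33 ± 0.12. Of 14 boundary genes, 10 rose, 0 fell and 4 did not pass (median 0.85, adjusted p = 0.00197, and 0.175 with an estimated correlation), with LSH3 at 1.94 ± 0.15 and BOP1 at 1.32 ± 0.12 besides CUC1 and CUC3. All 6 NAC genes targeted by miR164 rose (median 0.99, adjusted p = 0.00392, and 0.175 with an estimated correlation), including the senescence regulator NAC092 at 2.52 ± 0.14. Of 17 stress, defence and senescence genes, 11 rose, 1 fell and 5 did not pass (median 0.84, adjusted p = 0.00345, and 0.191 with an estimated correlation). PR1, a marker of salicylic acid responses, stood at 5.86 ± 0.21, HSP90.1 at 2.92 ± 0.14 and HSP70 at 2.19 ± 0.13, and SAG12, a marker of leaf senescence, was at least 47.1-fold higher because its DMSO signal was not above background. Adjusted over the list alone, 12 stress genes rose and 1 fell, and the counts of the other 7 lists were unchanged. With an estimated correlation in place of the preset one, camera called 0 of 23 lists in each of the 3 comparisons, and 5 lists in the Col-0 line, 4 in the cuc1 line and 1 in the difference had an unadjusted p under 0.05. The fry test, which does not compare a list with other genes, called 17, 18 and 5.

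The other 15 lists did not pass in the Col-0 line, and their members moved in both directions. Among 18 flavonoid and anthocyanin genes, 7 rose and 4 fell (camera adjusted p = 0.232), with DFR at 5.32 ± 0.44, the anthocyanin regulator PAP1 at 4.22 ± 0.22 and UGT78D1 at -1.66 ± 0.13. Among 8 CIN-type TCP genes, 3 rose and 5 fell (adjusted p = 0.372), and TCP10 (1.23) and TCP13 (0.89) rose besides TCP3. For 12 leaf polarity genes the counts were 2 and 6 (adjusted p = 0.232), with YAB5 at -2.21, and for 7 KNOX and shoot meristem genes 2 and 2 (0.791), with CLV1 at -2.02. The 7 GH3 genes, which conjugate auxin, gave 5 and 1 (0.198), with GH3.2 at 1.99 and GH3.10 at -2.50. The 16 cytokinin genes gave 4 and 7 (0.483), with the synthesis gene IPT7 at 2.74 and the degradation gene CKX1 at 2.54. Jasmonate synthesis genes gave 7 and 4 of 12 (0.487), with LOX4 at 3.51 and AOC3 at 2.62, and jasmonate response genes 8 and 2 of 16 (0.232), with JAZ7 at 2.40 and MYC2 at -1.77. Cell division genes gave 4 and 10 of 20 (0.232), leaf growth regulators 7 and 3 of 13 (0.145), with GRF7 at 2.52 and ANT at 1.22, and glucosinolate genes 6 and 8 of 17 (0.232), with MYB51 at 2.29 and MYB28 at -1.33. Cell wall loosening genes gave 1 and 6 of 12 (0.0972), with EXPA8 at -3.86, clock genes 1 and 6 of 12 (0.145), with ELF3 at -1.23, root markers 4 and 3 of 14 (0.617), with NRT2.1 at 3.84, and detoxification genes 2 and 1 of 8 (0.553), with CYP81D8 at 1.98 and GSTU25 at -1.17. The cell wall loosening list passed with the series matrix values (0.0261), median centring (0.0463), no filter on dim probes (0.0446), no dye term (0.0416), the Col-0 line fitted alone (0.0356) and outlying spots kept (0.0463). Adjusted over the list alone, 5 jasmonate synthesis genes and 9 glucosinolate genes fell, 8 leaf growth regulators rose, and the counts of the other 12 lists were unchanged. The median and the mean differed in sign for the CIN-type TCP (-0.46 and 0.19), KNOX (0.17 and -0.036), cytokinin (-0.16 and 0.0096), glucosinolate (-0.37 and 0.064) and root (-0.055 and 0.36) lists. For the first 4 of these the camera test followed the median, and for root markers the mean.

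In the Col-0 line 13691 of 24404 genes or probes passed, 6880 higher (50.3%) and 6811 lower, and 4916 of them changed at least 2-fold. With a locus were 12603 of these, 6279 higher and 6324 lower. Of the 13691, 39 had the opposite sign in the mean of the 3 Col-0 arrays, before the dye coefficient was taken off. The share of calls that were higher was 71.3% with the deposited series matrix values and 65.0% with median centring, which moved the median of all genes from 0.016 to 0.26 and 0.15. With the series matrix values the medians of the leaf polarity (0.088), cell division (0.00074), root (0.11) and detoxification (0.0090) lists turned from below to above 0, and with median centring those of the leaf polarity (0.0082) and root (0.0041) lists did. Medians of lists that passed kept their sign but moved in size. With the log ratios of the scanner software the SAUR median was -4.08, the stress median 2.08, the boundary median 1.37 and the class I TCP median -1.09. With the series matrix values the stress median was 1.79, the photosynthesis median -1.35, the Aux/IAA median -0.51 and the class I TCP median -0.50.

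**Figure D1:**
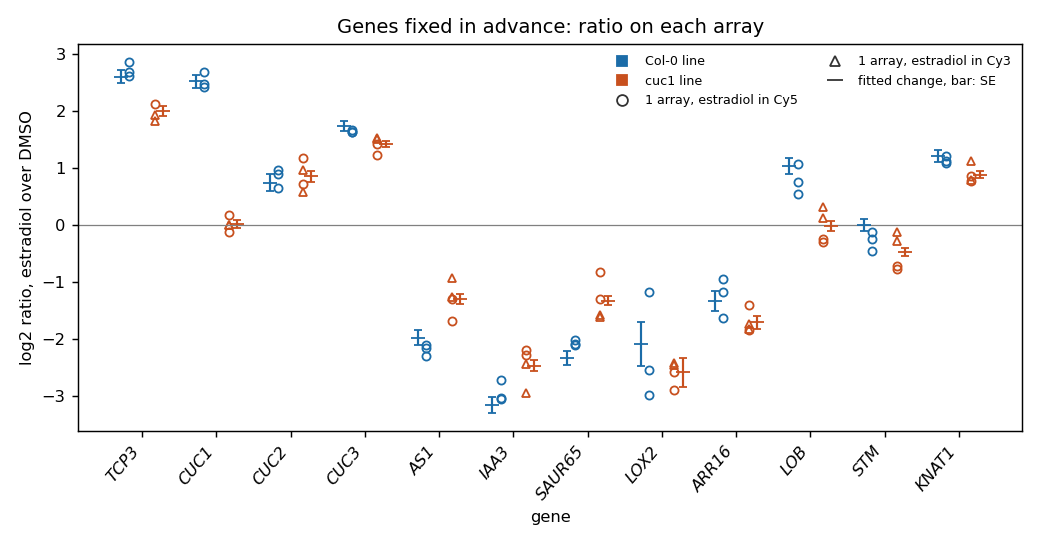
Log2 ratio of estradiol over DMSO on each array for the genes chosen in advance, with 3 Col-0 and 4 cuc1 arrays. Circles are arrays with estradiol in Cy5, triangles arrays with estradiol in Cy3, and dashes with bars the fitted change with its SE. CUC1 stood at 2.52 in the Col-0 line and at 0.017 in the cuc1 line, while IAA3 was below 0 on every array.

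The second comparison asked which transcripts changed after the same induction in seedlings that lack CUC1 function. The TCP3 signal rose 4.01-fold (log2 2.00 ± 0.08 SE, adjusted p = 2.5e-06) on 3 arrays with an accepted spot. On these its level was log2 15.20 to 15.43 under estradiol and 13.16 to 13.50 under DMSO. In the Col-0 line it was 15.27 to 15.48 and 12.40 to 12.80. The smaller rise went with a higher DMSO signal at a similar estradiol signal, with no test because line and slide coincided. The cuc1 arrays were brighter in both channels, with median signals of 140.5 to 191.5 in Cy3 and 268.5 to 323 in Cy5. On the Col-0 arrays these were 100 to 105.5 and 195.5 to 217. Since normalization was within each array, the TCP3 levels do not show which treatment differed between the lines. CUC1 did not pass, at log2 0.017 ± 0.072 (n = 4, adjusted p = 0.859). Its signal in the cuc1 line stood at log2 6.38 to 6.68 under estradiol and 6.44 to 6.52 under DMSO, against 9.69 to 9.74 and 7.05 to 7.27 in the Col-0 line, with no test because line and slide coincided. It was called well above background in 7 of 8 channels of the cuc1 line. The channel not so called stood at 6.50, within the range of the others. The CUC1 signal there thus lay near background, where a change may go unseen. CUC3 rose by 1.42 ± 0.06 and CUC2 by 0.86 ± 0.10. IAA3 changed by -2.46 ± 0.10, LOX2 by -2.58 ± 0.25, ARR16 by -1.70 ± 0.12, SAUR65 by -1.33 ± 0.08 and AS1 by -1.29 ± 0.09. KNAT1 rose by 0.89 ± 0.07, STM changed by -0.47 ± 0.07, and LOB stood at -0.019 ± 0.089 (adjusted p = 0.867).

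ARD3 again led the increases in the cuc1 line, at 96.0-fold (log2 6.59 ± 0.22, n = 4, adjusted p = 4.5e-07). AT5G19880 (6.30), TPPD (6.22), FMO1 (5.996) and AT5G24200 (5.90) also stood among the 10 largest increases of both lines. The others were the nitrate transporter gene NRT2.6 (6.23), SAG12 (5.89), AT3G22910 (5.81), BAP2 (5.61) and LEA7, a late embryogenesis abundant protein (5.60). AT3G22910 had no accepted spot on the Col-0 arrays and BAP2 had 1. The largest decreases were AT1G73600, annotated as a phosphoethanolamine methyltransferase (-3.88 ± 0.26), CYP71A22 (-3.74), CYP706A6 (-3.42), AT2G15020 (-3.41), AT1G73120 (-3.30), AT3G50270 (-3.30), AT2G10940 (-3.27), AGP30 (-3.25), AT3G54830 (-3.22) and AT3G52720 (-3.22).

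SAUR, Aux/IAA, class I TCP, photosynthesis and cell division genes fell and stress and NAC genes rose in the cuc1 line. Of 18 SAUR genes, 1 rose and 17 fell (median -1.31, camera adjusted p = 2.2e-07, and 0.368 with an estimated correlation), with SAUR14 at -2.96 ± 0.11 and SAUR63 at -2.40 ± 0.09. Of 25 Aux/IAA genes, 5 rose, 17 fell and 3 did not pass (adjusted p = 0.0208, and 0.594 with an estimated correlation), with IAA19 at -1.39 ± 0.07. Of 11 class I TCP genes, 0 rose, 8 fell and 3 did not pass (adjusted p = 0.00242, and 0.171 with an estimated correlation), with TCP9 at -2.12 ± 0.09 and TCP21 at -2.03 ± 0.06. Of 15 photosynthesis genes, 0 rose, 12 fell and 3 did not pass (median -1.23, adjusted p = 0.0208 from 7 members, and 0.594 with an estimated correlation), with RBCS2B at -3.15 ± 0.22 and RCA at -1.96 ± 0.14. Of 20 cell division genes, 4 rose, 13 fell and 3 did not pass (median -0.36, adjusted p = 0.0408, and 0.277 with an estimated correlation). KRP1, an inhibitor of division, was at -2.21 ± 0.09 among those that fell, beside the cytokinesis gene KNOLLE at -0.50 ± 0.05. The cyclin genes CYCD3;3 (0.73) and CYCD3;1 (0.68) rose.

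All 6 measured TCP3 targets named by earlier work also fell in the cuc1 line (median -1.96, adjusted p = 3.1e-04, and 0.171 with an estimated correlation), which is again not independent evidence. Of 6 NAC genes targeted by miR164, 5 rose and CUC1 did not pass (median 0.78, adjusted p = 0.0208, and 0.273 with an estimated correlation), with NAC092 at 2.58 ± 0.09. Of 18 stress, defence and senescence genes, 17 rose and 1 did not pass (median 1.71, adjusted p = 5.2e-05, and 0.171 with an estimated correlation), with PR1 at 3.76 ± 0.13, HSP17.6II at 2.43 ± 0.12 and HSP70 at 1.97 ± 0.08. Boundary genes did not pass as a list: 9 rose, 1 fell and 4 did not pass (median 0.37, adjusted p = 0.0703), with LSH3 at 1.12 ± 0.10 and LSH4 at -0.70 ± 0.07. Adjusted over the list alone, 18 Aux/IAA genes fell and 5 rose, and the counts of the other 8 of these lists were unchanged.

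Of the other 14 lists, leaf growth regulators gave 9 risen and 3 fallen genes of 13 (adjusted p = 0.0918), with GRF7 at 3.25 and ANT at 1.16. Cell wall loosening genes gave 3 and 8 of 12 (0.0918), with EXPA8 at -2.91, and glucosinolate genes 5 and 8 of 17 (0.0918), with MYB51 at 1.73. Flavonoid and anthocyanin genes gave 9 and 5 of 18 (0.318), with PAP1 at 4.26 and MYB111 at -2.08, cytokinin genes 5 and 7 of 16 (0.443), with CKX1 at 2.06 and ARR3 at 1.06, and GH3 genes 4 and 2 of 7 (0.242), with GH3.2 at 1.79. Jasmonate synthesis genes gave 6 and 5 of 12 (0.866), with LOX4 at 2.46, jasmonate response genes 7 and 7 of 16 (0.951), with JAZ7 at 1.39, clock genes 3 and 5 of 12 (0.242), with ELF3 at -0.55, and root markers 5 and 5 of 14 (0.705), with NRT2.1 at 3.35. CIN-type TCP genes gave 3 and 2 of 8 (0.951), KNOX and shoot meristem genes 2 and 3 of 7 (0.458), leaf polarity genes 2 and 4 of 12 (0.398), and detoxification genes 2 and 2 of 8 (0.318). Adjusted over the list alone, 5 GH3 genes rose and the counts of the other 13 lists were unchanged. The median and the mean differed in sign for jasmonate response genes (0.12 and -0.15) and root markers (-0.020 and 0.23), and with median centring the root median was 0.015.

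In the cuc1 line 14361 of 24458 genes or probes passed, 7467 higher (52.0%) and 6894 lower, and 3393 of them changed at least 2-fold. With a locus were 13269 of these, 6960 higher and 6309 lower. The call of the cell division list ended without cuc1 replicate 3 (adjusted p = 0.0580), with the log ratios of the scanner software (0.0545), with median centring (0.0569), with a stricter filter on dim probes (0.0750) and with each array scaled to a common spread (0.0510). That of the Aux/IAA list ended with the log ratios of the scanner software (0.0545). Boundary genes passed as a list without cuc1 replicate 4 (0.0377), with the replicate number as a fixed replicate block (0.0402) and with no filter on dim probes (0.0164). Cell wall loosening genes passed without cuc1 replicate 1 (0.0353) and with no filter (0.0440), and glucosinolate genes (0.0440) and leaf growth regulators (0.0259) with no filter. The SAUR median was -2.57 with the log ratios of the scanner software, and the stress median, above that of the Col-0 line here, was below it with those log ratios (1.73 against 2.08) and with the series matrix values (1.26 against 1.79).

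**Figure D2:**
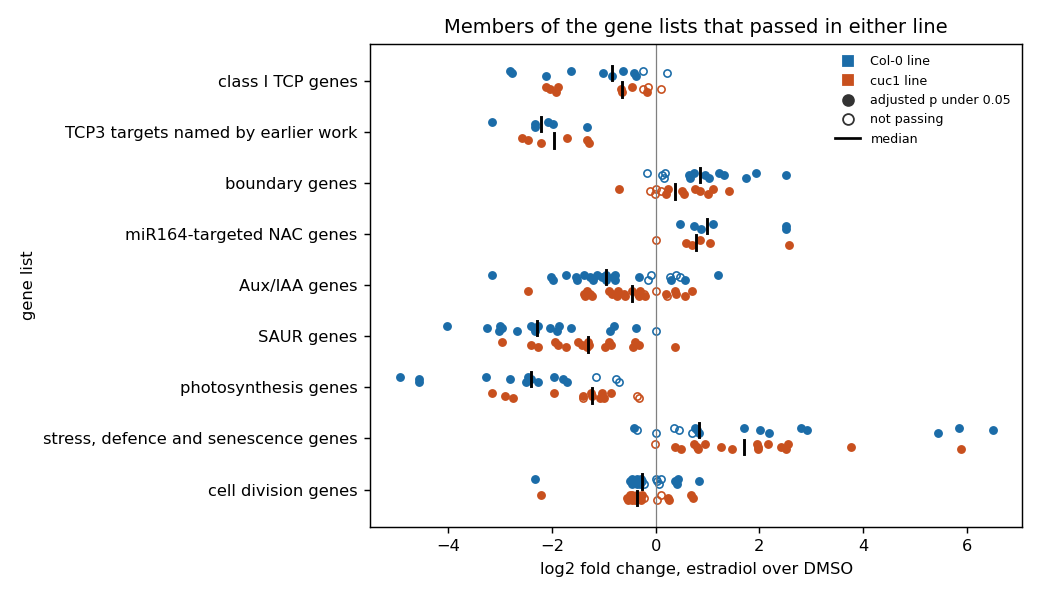
Log2 fold change of estradiol over DMSO of each member of the gene lists that passed in either line. Filled points passed at an adjusted p under 0.05, open points did not, and black lines are medians, for the Col-0 line (3 arrays) and the cuc1 line (4 arrays). SAUR genes had medians of -2.30 and -1.31, and stress genes of 0.84 and 1.71, an order that turned with the series matrix values (1.79 and 1.26) and with the log ratios of the scanner software (2.08 and 1.73).

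The third comparison asked whether the response itself differed between the lines, as Col-0 effect minus cuc1 effect. CUC1, with a signal near background in the cuc1 line, gave a difference of log2 2.51 ± 0.13 SE (adjusted p = 8.4e-04). LOB gave a difference of 1.06 ± 0.16 (adjusted p = 0.00928) and TCP3 of 0.60 ± 0.15 (adjusted p = 0.0452). SAUR65 (-0.9996 ± 0.14), IAA3 (-0.69 ± 0.17) and AS1 (-0.69 ± 0.16) were lowered more in the Col-0 line. STM differed by 0.48 ± 0.13 (adjusted p = 0.0450). CUC2 (-0.11 ± 0.18), CUC3 (0.32 ± 0.10), KNAT1 (0.33 ± 0.13), LOX2 (0.50 ± 0.46) and ARR16 (0.38 ± 0.21) did not pass. CUC1 and SAUR65 passed without any 1 array, with adjusted p up to 0.0103 and 0.0436. The call of TCP3 ended without Col-0 replicate 1 (adjusted p = 0.0763), 2 (0.125) or 3 (0.0896). It also ended without cuc1 replicate 1 (0.0899), although the TCP3 spot of that array was already missing. Without cuc1 replicate 2 the difference of TCP3 had no value. The call of LOB ended without cuc1 replicate 1 (0.0580) or 2 (0.0678). The calls of AS1 and IAA3 ended without Col-0 replicate 1 (0.0724 and 0.0927), 2 (0.0935 and 0.131) or 3 (0.0749 and 0.0593) or cuc1 replicate 1 (0.0560 and 0.141) or 2 (0.184 and 0.191). That of STM ended without Col-0 replicate 2 (0.151) or 3 (0.127) or cuc1 replicate 1 (0.1602) or 2 (0.206). Scaling each array to a common spread turned the difference of TCP3 to -0.014 (adjusted p = 0.974).

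The largest difference upward was that of NATA1, an acetyltransferase of ornithine, at 5.17 ± 1.23 (adjusted p = 0.0332), with 4.34 in the Col-0 line and -0.84, not passing, in the cuc1 line. The chitinase-like genes AT4G19750 (4.74 ± 0.32) and AT4G19760 (4.40 ± 0.26), close relatives whose probes were not shown to be distinct, followed with changes of 4.27 and 4.26 in Col-0 against -0.46 and -0.14, neither passing, in cuc1. AT2G25510 (3.45), PAD3 (3.39), TH8, a thioredoxin (3.31), AT1G19960 (3.19), AT5G42530 (3.11), AT5G03350 (3.00) and AT5G22555 (2.95) completed the 10. The largest differences downward were those of MRN1, a triterpene synthase (-3.08 ± 0.72), and of the copper and zinc superoxide dismutases CSD2 (-2.93 ± 0.57) and CSD1 (-2.31 ± 0.60) with their copper chaperone CCS (-2.23 ± 0.46). The replicates of the cuc1 line stood apart for these last 3, from 3.82 to -0.88 for CSD2. XTH26, a cell wall enzyme, fell in Col-0 (-1.40) and rose in cuc1 (1.23), as did FLA6, an arabinogalactan protein (-0.89 and 1.23), with differences of -2.63 ± 0.18 and -2.12 ± 0.24. AT2G10940 (-2.17), BBX14 (-2.14), Fes1B (-2.07) and the chlorophyll-binding protein gene CAB3 (-2.01) made up the rest. Of these 20 differences 10 passed without any 1 array. The calls that ended numbered 4, 8 and 7 without Col-0 replicates 1, 2 and 3, 7 and 6 without cuc1 replicates 1 and 2, and 0 without cuc1 replicate 3 or 4. The highest adjusted p without 1 array were 0.153 for NATA1, 0.154 for PAD3, 0.0650 for TH8, 0.162 for MRN1, 0.0596 for CSD2, 0.228 for CSD1, 0.109 for CCS, 0.0810 for AT2G10940, 0.0553 for Fes1B and 0.0773 for CAB3.

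SAUR genes and boundary genes differed as lists. Of 18 SAUR genes, 14 were lower in the difference, 0 higher and 4 not passing (median -0.90, camera adjusted p = 1.5e-09, and 0.718 with an estimated correlation), with SAUR20 at -0.97 ± 0.10 and SAUR64 at -1.06 ± 0.14. Adjusted over the list alone, 17 were lower. Here too the probes of related SAUR genes were not shown to be distinct. Of 14 boundary genes, 6 were higher and 8 did not pass (median 0.38, adjusted p = 0.00364, and 0.429 with an estimated correlation), and 7 were higher when adjusted over the list alone. Besides CUC1 and LOB these included LSH4 (0.87 ± 0.12) and KNAT6 (0.73 ± 0.13), a meristem gene. The call of LSH4 ended without cuc1 replicate 1 (adjusted p = 0.0541) and that of KNAT6 without Col-0 replicate 2 (0.0598) or 3 (0.0505) or cuc1 replicate 2 (0.101). CUC1 itself, mutated in 1 of the lines, is a member of this list. The medians kept their sign but not their size: that of boundary genes was 0.79 with the series matrix values, 0.83 with the log ratios of the scanner software and 0.15 with each array scaled to a common spread, and that of SAUR genes was -0.97, -1.71 and -0.42.

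The other 21 lists did not pass. Of 16 photosynthesis genes, 9 were lower and 7 did not pass (adjusted p = 0.0710 from 7 members), with RBCS1B at -1.80 ± 0.33 and LHCB5 at -1.60 ± 0.20, and 13 were lower when adjusted over the list alone. Of 25 Aux/IAA genes, 1 was higher and 6 lower (0.0710), with IAA19 at -0.63 ± 0.12, and 10 were lower over the list alone. Jasmonate response genes gave 3 higher and 0 lower of 16 (0.0710), with JAZ7 at 1.01 ± 0.12 and PDF1.2 at 2.93 ± 0.78, and clock genes 0 and 3 of 12 (0.174), with LUX at -0.79 ± 0.12. Stress, defence and senescence genes gave 2 and 3 of 17 (0.951), with PR1 at 2.097 ± 0.25, PR5 at 1.65 ± 0.17 and the cold regulator CBF3 at -1.46 ± 0.33. The remaining counts were 1 and 2 of 8 for CIN-type TCP (0.261), 0 and 3 of 11 for class I TCP (0.743), 0 and 3 of 6 for the TCP3 targets named by earlier work (0.289) and 1 and 0 of 6 for NAC genes (0.418). They were 2 and 1 of 7 for KNOX (0.333), 1 and 2 of 12 for polarity (0.328), 0 and 1 of 7 for GH3 (0.934), 1 and 2 of 16 for cytokinin (0.743), with ARR3 at -1.31 ± 0.12, and 2 and 0 of 12 for jasmonate synthesis (0.328). For cell division they were 0 and 0 of 20 (0.328), for leaf growth 0 and 1 of 13 (0.743), with GRF7 at -0.73 ± 0.16, for flavonoids 0 and 0 of 18 (0.354) and for glucosinolates 1 and 0 of 17 (0.704). For root markers they were 0 and 0 of 14 (0.933), for cell wall loosening 2 and 4 of 12 (0.328), with EXPA3 at -1.24 ± 0.18, and for detoxification 1 and 0 of 8 (0.768). In the 3 lists where limma called 0 genes, 3 cell division, 6 flavonoid and 3 root genes had an unadjusted p under 0.05. Adjusted over the list alone, 3 CIN-type TCP, 5 polarity, 4 cytokinin, 6 cell wall and 4 stress genes were lower, 2 cytokinin and 2 clock genes were higher, and the other counts of these 21 lists were unchanged. The median and the mean differed in sign for the GH3 (0.034 and -0.041), leaf growth (0.0060 and -0.071), root (-0.093 and 0.14) and stress (-0.052 and 0.14) lists. Among the genes named here, the calls of LUX (adjusted p = 0.0640) and EXPA3 (0.0605) ended without cuc1 replicate 1. That of PDF1.2 ended without Col-0 replicate 1 (0.0973) or 2 (0.1397) or cuc1 replicate 1 (0.213) or 2 (0.135), and that of CBF3 without Col-0 replicate 1 (0.0604), 2 (0.0932) or 3 (0.0849) or cuc1 replicate 1 (0.0943). RBCS1B lost its call without Col-0 replicate 2 (0.0609) or 3 (0.0529) or cuc1 replicate 1 (0.0736) or 2 (0.102). Without Col-0 replicate 2 or cuc1 replicate 1 or 2 those of IAA19 (0.0745, 0.0893 and 0.117) and GRF7 (0.0775, 0.155 and 0.0838) ended as well. The photosynthesis list passed without Col-0 replicate 1 (adjusted p = 3.9e-04) or cuc1 replicate 1 (0.0329), 2 (0.00133) or 4 (0.0221), and with the series matrix values (2.1e-08), outlying spots kept (2.0e-05), the fixed replicate block (9.8e-04), no filter (0.0256) and median centring (0.0373). The Aux/IAA list passed without Col-0 replicate 3 (0.0152) or cuc1 replicate 2 (0.0269) or 4 (0.0255), and with the series matrix values (0.0108), outlying spots kept (0.0156), no filter (0.0256) and the fixed replicate block (0.0293). The jasmonate response list passed without Col-0 replicate 3 (0.0152) or cuc1 replicate 1 (0.00675), and with the fixed replicate block (0.00308), no dye term (0.00589) and no filter (0.0256).

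The response differed for 3470 of 24437 genes or probes, 1519 higher in the Col-0 line (43.8%) and 1951 lower, and 720 of them differed at least 2-fold. With a locus were 3261 of these, 1381 higher and 1880 lower. With the dye term, this difference equals the mean of the 3 Col-0 arrays minus the mean of cuc1 replicates 1 and 2, which share their dye orientation, and cuc1 replicates 3 and 4 entered only the residual spread; it held for all 24437 within 1e-06. The count was accordingly 650 and 611 without cuc1 replicates 1 and 2, 5389 without either of cuc1 replicates 3 and 4, and 2263, 759 and 1266 without Col-0 replicates 1, 2 and 3. Without the dye term, which brings in all 4 cuc1 arrays, 3704 passed, 2506 of the 3470 (72.2%) among them, and the differences of IAA3 (adjusted p = 0.124), STM (0.483), MRN1 (0.0855), CAB3 (0.0896), TH8 (0.0651), LHCB1.1 (0.172), CBF3 (0.141), ELF3 (0.269), CSD1 (0.598), CSD2 (0.470) and CCS (0.374) no longer passed. For TCP3, TCP7, CAB3, LHCB5, LHCA2 and LHCB1.1 the cuc1 side of the difference rested on 1 array, the spot on the other array of that orientation being an outlier. The share of calls higher in Col-0 was 89.6% with the series matrix values and 76.7% with median centring, which moved the median of all differences from -0.011 to 0.21 and 0.10.

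The responses of the lines were alike across genes, which are not independent replicates: over 24404 genes or probes the fitted changes correlated at Pearson r = 0.918 and Spearman rho = 0.858. Among them 5558 were higher in both lines, against 2098 for independent lists, and 5432 lower in both, against 1922. Of 11153 that passed in both lines, 163 had opposite signs, XTH26 and FLA6 among them. Of the 10990 with the same sign, 8849 (80.5%) changed more in the Col-0 line, and the least-squares slope of the cuc1 change on the Col-0 change was 0.708. Error in the Col-0 changes, which hold that of the dye coefficient, lowers this slope and can raise that share. Among 3462 with a value in every comparison whose response differed, 2287 passed in both lines with the same sign, of which 2130 changed more in the Col-0 line and 157 more in the cuc1 line. A further 673 passed in the Col-0 line alone, 339 in the cuc1 line alone and 163 in both with opposite signs. The SD of the log2 ratios of an array was 1.02 ± 0.018 (SD, n = 3) on the Col-0 arrays and 0.815 ± 0.067 (n = 4) on the cuc1 arrays, with a two-sided exact permutation p of 0.0286 over 35 splits, the smallest they can give. The Col-0 arrays lay on 1 slide and the cuc1 arrays on another, so line and slide cannot be told apart.

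**Figure D3:**
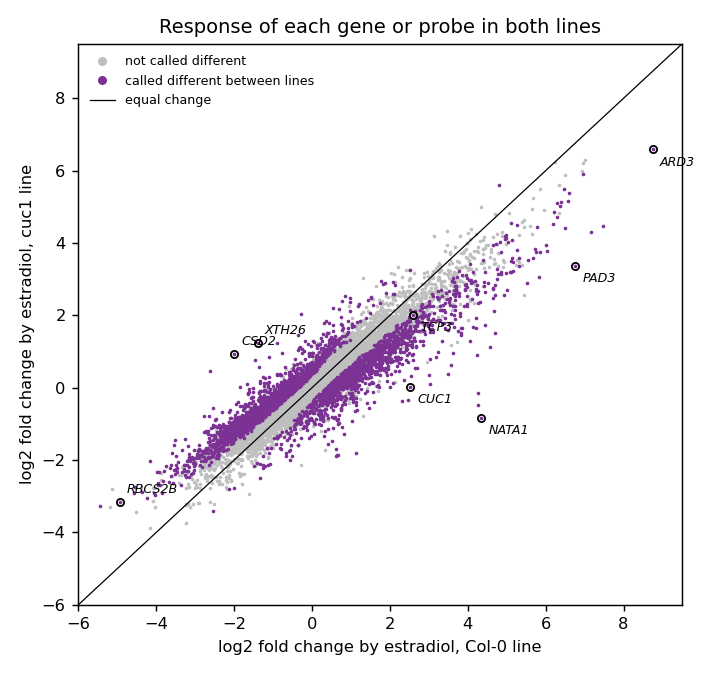
Log2 fold change by estradiol in the cuc1 line (y axis) against that in the Col-0 line (x axis) for each of 24404 genes or probes, coloured by whether the response differed at an adjusted p under 0.05. The line marks equal change. The points follow a slope of 0.708, flatter than the line of equal change.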

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

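The tests of spike-in slopes, shared slides, dye orientations and detoxification genes, those of the gap between arrays and of the model without the dye term for CSD1, CSD2 and CCS, and the scaling of arrays to a common spread were chosen after the result was seen.

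As lists, boundary genes lay higher (camera adjusted p = 0.00364) and SAUR genes lower (1.5e-09) in the Col-0 line than in the cuc1 line, neither with an estimated correlation, and stress (0.951), photosynthesis (0.0710) and Aux/IAA genes (0.0710) did not pass. Of 12 measured genes fixed in advance, 7 differed by limma's test of the difference itself. The 7 include CUC1, mutated in the cuc1 line, and TCP3, which the transgene carries. Among the 7, CUC1 and SAUR65 alone kept their call without each single array. Genes given beside the 12 were chosen for their test, 20 as the largest differences that passed and 13 as list members with the smallest p, so their passing is no further evidence. Among those higher in the Col-0 line were the defence genes NATA1 (log2 difference 5.17), PAD3 (3.39), PR1 (2.097) and PR5 (1.65), the chitinase-like genes AT4G19750 (4.74) and AT4G19760 (4.40), and the boundary and meristem genes CUC1 (2.51), LOB (1.06), LSH4 (0.87), KNAT6 (0.73) and STM (0.48). TCP3 (0.60), TH8 (3.31), AT2G25510 (3.45), AT1G19960 (3.19), AT5G42530 (3.11), AT5G03350 (3.00) and AT5G22555 (2.95) were also higher. Among those lower in the Col-0 line were SAUR21 (-1.18), SAUR64 (-1.06), SAUR65 (-0.9996), SAUR20 (-0.97), IAA3 (-0.69) and AS1 (-0.69), and the photosynthesis genes CAB3 (-2.01), LHCB1.1 (-1.86), RBCS1B (-1.80), LHCB5 (-1.60) and LHCA2 (-1.46). XTH26 (-2.63) and FLA6 (-2.12) of the cell wall, CBF3 (-1.46) and RD29B (-0.48) of stress responses, CSD2 (-2.93), CSD1 (-2.31) and CCS (-2.23) of copper use, and MRN1 (-3.08), AT2G10940 (-2.17), BBX14 (-2.14) and Fes1B (-2.07) were lower as well. Without the dye term the calls of IAA3, STM, MRN1, CAB3, TH8, LHCB1.1, CBF3, CSD1, CSD2 and CCS ended. Of the 40 differences, 18 kept their call without each single array that left a value. The calls that ended numbered 9, 18 and 17 without Col-0 replicates 1, 2 and 3, 16 and 15 without cuc1 replicates 1 and 2, and 0 without cuc1 replicate 3 or 4.

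Single arrays stood apart for 5 of 105 groups of 4 cuc1 values, where 1 in 20 by chance gives 5.25. Replicate 4 was the outlying array for YAB5 (log2 ratio -2.05, others -1.37 to -1.34), RBCS2B (-4.24, others -2.90 to -2.74) and RHD6 (1.35, others 0.72 to 0.78). Replicate 2 was it for GH3.17 (1.44, others 1.67 to 1.69) and replicate 1 for PRR5 (0.61, others 0.41 to 0.44). Groups of 3 arrays, as in the Col-0 line, were not tested.

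For the genes changed within a line, the sign patterns of the ratios were too few for a share under 0.05. Of 4 patterns in the Col-0 line 1 gave as many calls, the real one with 13691, and the highest other gave 1. Of 7 patterns in the cuc1 line 1 did, the real one with 14361, and the highest other gave 21.

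Responses to estradiol were smaller in the cuc1 line, with a slope of 0.708 on the Col-0 response, which error in the Col-0 changes lowers in part. Of 35 splits of the 7 arrays 1, the real one, gave as many as 3470 differing genes, and the highest other, which moved only cuc1 replicate 4 to the Col-0 side, gave 2818, but the 5 arrays that enter the difference allow 10 splits, too few for a share under 0.05, where limma called 0 genes in the highest other (2574 at an unadjusted p under 0.05, against 7600 in the real one). The tables argue against compressed ratios on the slide of the cuc1 arrays. Its spike-in slopes were 1.01 times those of the Col-0 arrays (0.942 against 0.934). The tables also argue against 1 factor that multiplied every response alike as the whole cause. After each array was scaled to a common spread, 2031 genes differed (58.5% of the count, 1665 of them among the 3470). This scaling tests a proportional change only, so weaker induction that did not act on all genes in proportion stays open. A common factor for part of the pattern stays open, since the scaling raises the slope by construction. With 0 slides holding both lines, slide and scan cannot be told apart from the line, and the loss of CUC1, the difference the design names, stays open and untested.

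Stress, defence and senescence genes rose in both lines, 11 of 17 in the Col-0 line and 17 of 18 in the cuc1 line. With an estimated correlation the list passed in neither line (camera adjusted p = 0.191 and 0.171). The tables argue against a bias of single probes for 1 dye, since 17 of 18 members were above 0 in both dye orientations of the cuc1 arrays. A response to estradiol or its solvent stays open, since no line without the transgene was treated. Such a response could also raise detoxification genes, whose list did not pass (adjusted p = 0.553 in the Col-0 line and 0.318 in the cuc1 line), which decides nothing. A response to the induced repressor, the biological explanation the design gives, was not tested apart from it.

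CSD1, CSD2 and CCS rose on cuc1 replicates 1 and 2 above their level on the other arrays, with CSD2 at 3.82 and 1.51 there and at -0.88 and -0.77 on cuc1 replicates 3 and 4. The growth protocol of cuc1 replicates 1 and 2 gave 5 mM estradiol for 1 channel, and a difference in dose was not tested. The tables argue against a probe bias for 1 dye as the whole cause. Arrays of 1 orientation lay up to 2.00, 2.31 and 1.48 apart for the 3 genes, above the 99th percentile of all features (1.34). An earlier bound on the dye coefficient of FSD1, beyond -1, had not been met (-0.449). A dye bias beside other causes stays open, since both cuc1 arrays with estradiol in Cy5 lay above both with it in Cy3. A candidate explanation is copper supply, or another condition, that differed between the 2 channels of some cuc1 replicates, since FSD1, which copper shortage raises while it lowers the 3 genes, differed by -1.64 between the arrays with the highest and the lowest CSD2 ratio, which differed by 4.70 in CSD2. Among the cuc1 arrays FRO5 (-2.96, -1.14, 1.53 and -0.61 on replicates 1 to 4), ZIP2 (-1.47, -0.63, 0.44 and 0.39) and COPT2 (-1.71, -1.69, -0.26 and -0.97), copper genes looked at after the data were seen, ran in the order opposite to CSD2. The copper chaperone gene CCH stood at 0.93 to 1.41, and cuc1 replicate 4, with CSD2 about as low as replicate 3, had FSD1 at -1.05, near replicate 2 (-1.21). On the Col-0 arrays CSD2 was not raised (-0.18, -0.023 and -0.59), yet COPT2 was about as low as on cuc1 replicates 1 and 2 (-1.67, -1.42 and -1.63). ZIP2 (0.42, 0.14 and 0.42) and FRO5 (-0.12, 0.098 and 0.20) were not low there. A difference between the lines stays open as well, since without the dye term 0 of 3 genes were called, with differences of -0.80, -1.18 and -1.03 (limma adjusted p = 0.598, 0.470 and 0.374) that kept their sign.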

How the results depend on the processing

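Scaling each array to a common spread was the 1 alternative chosen after the results were seen. The named genes of the Col-0 line gave the same direction and side of the threshold in 2153 of their tests under other settings, and those of the cuc1 line in 2178. In the Col-0 line 8 weakened, 4 passed newly and 10 that had not passed changed sign, and in the cuc1 line 5 of the last kind did. For the differences 1651 stayed, 311 weakened, 76 passed newly and 16 that had not passed changed sign. Those of GRF7 with the series matrix values (0.14, adjusted p = 0.640) and of TCP3 with scaled arrays (-0.014, adjusted p = 0.974) reversed, and the cause was not tested.

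Counts of changed genes stayed within 1.5 times the value reported, except 4916, 3393 and 720 with a 2-fold minimum, which by construction calls fewer. Without 1 array they ran from 11157 to 13879 in the Col-0 line and from 12010 to 14349 in the cuc1 line. The count of differences depended on the setting. It was 5502 with the series matrix values (1935 shared), where the median difference of all genes was 0.21, 2031 with scaled arrays (1665 shared) and 1849 with a random replicate block (all 1849 shared). Without 1 array it ran from 611, without cuc1 replicate 2, to 5389, without cuc1 replicate 3 or 4, and was 2263, 759 and 1266 without Col-0 replicates 1 to 3 and 650 without cuc1 replicate 1. The difference rests on the 3 Col-0 arrays and on cuc1 replicates 1 and 2, so leaving out 1 of these leaves fewer arrays.

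With a fixed replicate block in place of the dye term, 12881, 12232 and 3095 genes passed in the Col-0 line, the cuc1 line and the difference, the last with 2258 shared. Deviations of arrays with the same replicate number correlated across genes at -0.155, -0.156 and -0.0661, and the random block gave a correlation of -0.303, so nothing in the values paired the numbers.

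Lists differing between the lines numbered 4 with the series matrix values or with outlying spots kept, 5 with no filter or with the fixed replicate block, 0 with an estimated correlation, and from 2 to 4 without 1 array. There were 4 without Col-0 replicate 3 or cuc1 replicate 1, 2 or 4. SAUR and boundary genes passed in each of these but the estimated correlation, and photosynthesis, Aux/IAA or jasmonate response genes joined them. An estimated correlation also left 0 lists in the Col-0 line and 0 in the cuc1 line, where the other settings gave 7 to 9 and 6 to 12. By camera 5, 4 and, for the difference, 1 list then had an unadjusted p under 0.05. The values argue against a higher correlation of members as the whole cause. The estimate was 0.0021 for class I TCP genes, -0.0069 for boundary genes and -0.118 for TCP3 targets. These lie under the preset 0.01, yet the calls of these lists in the Col-0 line ended too. What else ended them was not tested.

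The correlation of the 2 responses was 0.897 with the scanner log ratios and 0.898 with the series matrix values, against 0.903 to 0.926 without 1 array, and the slope was 0.878 with scaled arrays and 0.671 to 0.725 under the other settings. The cause was not tested for the correlation, whereas the scaling equalizes spreads by construction. Fits of each line alone gave no difference, and a slide block was not run. Signal over background limited the dim genes, and a ratio against a channel at background is a bound.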

Other observations

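All tests of this part, on 25 gene families in 3 comparisons, were chosen after the data were seen. Proteasome subunit genes rose and pentatricopeptide repeat, kinesin and tubulin genes fell in both lines by camera with its preset correlation. With an estimated correlation none of these calls held (adjusted p = 0.224, 0.490, 0.558 and 0.558 in the Col-0 line and 0.215, 0.447, 0.612 and 0.612 in the cuc1 line). With median centring and the series matrix values, where no test of families was run, their medians kept their sign, down to -0.086 for tubulin in the Col-0 line. Of 62 proteasome subunit genes, 48 rose and 1 fell in the Col-0 line (median log2 change 0.67, camera adjusted p = 2.5e-08) and 49 rose and 2 fell in the cuc1 line (0.41, 1.1e-07). Of 426 pentatricopeptide repeat genes, which mostly act on RNA of plastids and mitochondria, 15 rose and 242 fell (-0.31, 7.1e-11), and 24 rose and 220 fell in the cuc1 line (-0.17, 5.4e-08). Kinesin motor genes gave 2 higher and 35 lower of 45 (-0.46, 1.0e-06), and 5 and 32 in the cuc1 line (-0.35, 2.1e-05). Tubulin genes gave 1 and 16 of 28 (-0.45, 0.00520), and 2 and 14 of 29 in the cuc1 line (-0.18, 0.0305).

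WRKY, NAC and late embryogenesis abundant genes rose in both lines, whereas MYB genes did not pass in either (camera adjusted p = 0.464 and 0.0613). With an estimated correlation none of the former held (0.490 each in the Col-0 line and 0.435, 0.215 and 0.215 in the cuc1 line). Ubiquitin-conjugating or U-box genes passed in the Col-0 line (0.0445, and 0.646 with an estimated correlation) and not in the cuc1 line (0.0613). WRKY genes gave 44 higher and 10 lower of 69 in the Col-0 line (median 0.73, camera adjusted p = 2.6e-05) and 44 and 11 in the cuc1 line (0.61, 2.1e-05). NAC genes gave 47 and 15 of 83 (0.50, 0.00202) and 51 and 15 of 84 (0.41, 7.2e-05), and late embryogenesis abundant genes 15 and 4 of 29 (0.54, 0.0333) and 24 and 3 (0.63, 5.4e-05). The plastid ribosomal proteins gave 0 higher and 24 lower of 38 in the cuc1 line (-0.66, 0.00212, and 0.612 with an estimated correlation) and did not pass in the Col-0 line (4 and 18 of 38, 0.0850). Their difference between the lines did not pass either, with 1 higher and 14 lower of 38 (median -0.18, camera adjusted p = 0.773). In the difference between the lines 8 families passed, none with an estimated correlation (0.602 or 0.681). Cytosolic ribosomal protein genes lay higher in the Col-0 line (adjusted p = 6.6e-07 from 170 genes), although 15 of 228 were higher and 213 did not pass one by one. Their median difference was 0.23, 0.56 with median centring and 0.39 with the series matrix values. This family was lower in the cuc1 line (10 higher and 33 lower of 223, median -0.12, 0.0240, and 0.706 with an estimated correlation) and did not pass in the Col-0 line (35 and 13 of 222, 0.0850). Proteasome (9.2e-05, 6 of 62 higher one by one), glutathione transferase (0.00291, 9 of 47 higher and 1 lower), WRKY (0.0104, 17 of 69 higher and 2 lower) and ubiquitin-conjugating or U-box genes (0.0348, 4 of 48) also lay higher there. Kinesin (0.00230, 6 of 45 lower one by one) and tubulin genes (0.0137, 7 of 28) lay lower, with medians of -0.0036 and -0.0095 with the series matrix values, and so did pentatricopeptide repeat genes (3.8e-06, 41 of 426 lower and 5 higher), whose median turned to 0.017 with those values.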
